A study of Mus musculus with 24 samples.

How the data were processed

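RNA from skin and bone of female mice was sequenced by the authors as polyA-selected libraries on an Illumina HiSeq instrument with 2 x 150 base pair reads, per the labels. The 24 libraries form 6 groups of 4 biological replicates: skin and bone, each F-PRT, S-PRT or Untreated. The labels give no strain, dose, time after irradiation or library strand. The submitters' processing notes name FastQC, cutadapt, STAR, RSEM and the build GRCm38; the versions, roles and order of these tools are not given in the sources used here. Each deposited file holds RSEM gene results for 55471 genes. Expected counts, TPM and FPKM are the 3 units of the deposited files per the file headers. The expected counts were used, rounded to whole numbers, and TPM and FPKM entered no test. The annotation release behind the files is not stated; names, biotypes and positions came from GENCODE M21, which matched 55230 of the 55471 identifiers (99.57%), and 241 had no match.

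Total expected counts ran from 10.91 to 22.09 megacounts per library. Replicate pairs within a group differed by more than counting error in every group, with a chi-square per degree of freedom from 9.54 to 210 over genes with at least 20 counts, and no pair within a group was so close as to be the same library sequenced again. Standard errors of log2 changes came from the edgeR fit and include the spread between libraries. The floor of 3 counts covers counting error alone, and reads without molecular identifiers are not independent molecules. RSEM divides reads among near-identical genes, so values of single members of such families are less certain.

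Genes were tested with edgeR 4.0.16 in R 4.3.3, with a quasi-likelihood F test on the 12 libraries of each tissue, TMM scaling, the filterByExpr filter of the package and a Benjamini-Hochberg adjusted p threshold of 0.05. The comparisons were F-PRT against Untreated, S-PRT against Untreated and F-PRT against S-PRT in each tissue. The difference of each of the 3 effects between skin and bone was tested as an interaction on all 24 libraries. CPM values carry TMM scaling, and log2 CPM values use a prior count of 2. The 39 gene lists of cell types and pathways were written from general knowledge, and a list was tested where at least 5 members were. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and beside it with the correlation estimated from the libraries and with fry. Library measures were the shares of counts from 7SK, 7SL, rRNA-like, mitochondrial and protein-coding genes.

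Genes were named by rule. A panel (Cdkn1a, Mdm2, Ccng1, Mki67 and Tgfb1, with Krt6a and Krt1 in skin and Col1a1, Ctsk and Col2a1 in bone) was looked up in each comparison. The 6 largest rises and 6 largest falls were taken among genes past the test with a mean of at least 2 CPM and no overlap between the groups, leaving out models named Gm or Rik, pseudogenes and immunoglobulin and T cell receptor segments. Up to 3 members of smallest p were taken from the 4 higher and 4 lower lists past the test, and up to 2 from the p53, cell cycle and keratinocyte or osteoclast lists where these did not pass. Where fewer than 5 genes passed, all were named together with the 5 of smallest p. For the interaction the 5 of smallest p among those past the test were named; for F-PRT against S-PRT, where 0 passed, the 3 of smallest p were named outside this rule. Panel genes whose value with all libraries is not in the report did not pass there. After F-PRT these were Tgfb1 in skin and bone (adjusted p = 0.396 and 0.367), Krt6a and Krt1 in skin (0.646 and 0.807) and Col2a1 in bone (0.28, but 0.0346 without F-PRT 3, 0.0365 without Untreated 1 and 7.45e-05 without the libraries in doubt). After S-PRT they were Tgfb1, Krt6a and Krt1 in skin (0.91, 0.808 and 0.568), Mki67 in skin (0.548), and Mdm2 and Tgfb1 in bone (0.179 and 0.234, the last 0.024 with voom and 0.0448 without Untreated 1). Between the beams each stood at adjusted p = 0.999 in skin and 1 in bone. Pecam1, Col1a2, Krt14, the satellite-like gene models, and the untreated level of Slfn4 were chosen after their values were seen.

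These steps, the lists, the naming rule and the following alternatives were set before the data were examined: DESeq2 1.42.0, limma voom with quality weights, RLE scaling, no filter, a filter of 1 CPM in 4 libraries, a replicate block, a skeletal muscle covariate, the 8 compared libraries alone, leaving out each library, and untreated libraries split 2 and 2. Added after the data were seen were fits without 5 libraries in doubt (skin S-PRT 4 and Untreated 1, bone F-PRT 2, F-PRT 3 and Untreated 1), without 7SK, 7SL and rRNA-like models, and with a keratinocyte differentiation covariate in bone. RLE scaling moved no named gene or list across the test except the bone chondrocyte list after F-PRT, which no longer passed.

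The workflow was tested on simulated data with the design, depth and spread of each tissue and 200 changed genes. edgeR recovered 3 of 67 genes changed 1.5-fold, 22 of 67 changed 2-fold and 61 of 66 changed 4-fold between F-PRT and Untreated in skin, and 23, 45 and 65 in bone. In the simulated skin data edgeR made 87 calls of which 1 was false for F-PRT against Untreated, and 0 calls for S-PRT against Untreated, where no gene was changed. DESeq2 made 172 calls of which 40 were false, and 14 false calls where no gene was changed, and voom made 86 of which 2 were false. In bone edgeR made 138 calls of which 3 were false, DESeq2 189 of which 27 were false and voom 134 of which 1 was false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.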

Results

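RNA was sequenced from skin and bone of female mice 10 weeks old, with polyA selection, in a series titled for a mouse sarcoma model. In each tissue 4 libraries carried the label F-PRT, read here as FLASH proton radiotherapy, a proton beam given at an ultra-high dose rate. Another 4 carried the label S-PRT, read here as standard proton radiotherapy at the conventional dose rate, and 4 came from untreated mice. The 24 libraries thus fell into 6 groups. The 4 libraries of a group are biological replicates per the labels, and n = 4 for each mean below unless another n is given. Total expected counts, in megacounts (M), ran from 16.42 to 22.09 M per skin library and from 10.91 to 17.36 M per bone library. By group they spanned 16.42 to 21.61 M in skin F-PRT, 18.8 to 22.09 M in skin S-PRT and 16.71 to 21.2 M in skin Untreated. In bone the ranges were 15.15 to 16.58 M for F-PRT, 13.83 to 17.36 M for S-PRT and 10.91 to 16.21 M for Untreated. Levels are given as scaled counts (CPM) with their SD, and log2 changes with their standard error (SE). The question set by the series title was which expression changes follow F-PRT and S-PRT and where these differ. Positions are those of GRCm38, and the counts do not separate the strands of overlapping genes.

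Skin after F-PRT was set against untreated skin to ask what FLASH irradiation changed there. Targets of p53, the transcription factor that answers DNA damage, rose: of 30 measured, 19 rose, 0 fell and 11 did not pass, and 24 rose adjusted over the list alone. Trp53inp1 (ENSMUSG00000028211, chromosome 4, 11156431 to 11174379), a p53-induced regulator of cell death, stood at 298 ± 43.1 CPM in F-PRT and 72.4 ± 9.02 CPM in Untreated, a 4.11-fold rise (log2 2.04, SE 0.16, adjusted p = 2.74e-05). Ccng1, which encodes cyclin G1, rose 3.3-fold from 96 ± 27.6 to 317 ± 47.7 CPM (adjusted p = 0.00221), and Dcxr, a carbonyl reductase, rose 5.16-fold (log2 2.37, SE 0.22, adjusted p = 8.55e-05). Zmat3, an RNA-binding p53 target, rose 2.42-fold (adjusted p = 8.36e-05), and Mdm2, the ligase that restrains p53, rose 1.64-fold (log2 0.71, SE 0.10, adjusted p = 0.00221). The list passed with a median log2 change of 0.98 (adjusted p = 8.05e-49) and also passed at adjusted p = 0.00112 with an estimated correlation. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the p53-driven brake on the cell cycle, was at 326 ± 14.6 CPM against 175 ± 70.2 CPM (1.86-fold, log2 0.90, SE 0.20, adjusted p = 0.0377). In that untreated group replicate 1 held 280 CPM of Cdkn1a and the others 135 to 149 CPM. The Cdkn1a call was lost on leaving out F-PRT 1, 2, 3 or 4, S-PRT 1, 2 or 3, or Untreated 2, 3 or 4 (adjusted p 0.0558 to 0.144) and with the muscle covariate (log2 0.90, adjusted p = 0.0531).

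Lipid synthesis and wound genes fell in F-PRT skin. Of 28 sebaceous gland and skin lipid genes, 8 fell, 0 rose and 20 did not pass, with 20 falling adjusted over the list alone and a median log2 change of -0.93 (adjusted p = 1.69e-19, but adjusted p = 0.307 with an estimated correlation). The cholesterol pathway enzymes Idi1 (341 ± 35.3 to 136 ± 10.8 CPM, 0.399-fold, adjusted p = 0.00103) and Hmgcs1 (0.513-fold, adjusted p = 0.00124) were among those that fell. Of 29 measured wound and stress keratinocyte genes 5 fell, 0 rose and 24 did not pass, and 14 fell adjusted over the list alone. Their median log2 change was -1.03 (adjusted p = 1.28e-10, but adjusted p = 0.287 with an estimated correlation). Krt16, a keratin of stressed epidermis, fell from 156 ± 53 to 53.2 ± 7.1 CPM (0.341-fold, log2 -1.55, SE 0.23, adjusted p = 0.00294). Fabp5, an epidermal fatty acid binding protein, fell to 0.441-fold (adjusted p = 0.0131). S100a8, an alarmin of neutrophils and stressed keratinocytes, fell from 13.6 ± 10.1 to 2.45 ± 1.08 CPM (adjusted p = 0.0207). Fabp5 lost its call without F-PRT 1 (adjusted p = 0.064) or Untreated 2 (adjusted p = 0.0528), and S100a8 lost its call without F-PRT 1, 3 or 4 or Untreated 2 (adjusted p 0.0664 to 0.0889). Untreated 1, which held the most rRNA-like counts of the skin libraries at 10.5%, also held the highest keratinocyte differentiation level of the skin libraries at 8.14 (mean log2 CPM).

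The largest rises in F-PRT skin under the naming rule were in genes of low level in untreated skin. Ms4a10 (ENSMUSG00000024731, chromosome 19, 10962293 to 10974670) had 4 counts over the 4 untreated libraries and 4.21 ± 0.85 CPM after F-PRT (fitted 65.8-fold, adjusted p = 8.55e-05). Anks1b, a neuronal scaffold gene, rose 33.2-fold (log2 5.05, SE 0.37, adjusted p = 2.74e-05). Gria3 (ENSMUSG00000001986, chromosome X, 41400854 to 41678601), a glutamate receptor subunit, rose from 2.85 ± 0.27 to 50.5 ± 3.72 CPM, a 17.7-fold change (log2 4.14, SE 0.16, adjusted p = 4.52e-08). Gapdhs, the sperm form of a glycolytic enzyme, rose 17.1-fold, Krt7, a keratin of simple epithelium, 13.2-fold and Celf5, an RNA-binding protein of neurons, 9.84-fold (adjusted p from 2.74e-05 to 8.55e-05). The largest falls were in Cyp2g1, a cytochrome P450 gene, from 274 ± 108 to 26.6 ± 12.7 CPM (0.0971-fold, adjusted p = 0.0038), and in Akr1c18, a steroid reductase, at 0.143-fold (adjusted p = 0.00189). Ccl27b, a skin chemokine gene, fell to 0.189-fold (adjusted p = 8.55e-05), Chil1, a chitinase-like protein, to 0.175-fold (adjusted p = 0.0343) and Sprr2i, a cornified envelope gene, to 0.176-fold (adjusted p = 0.0124). Sprr2i has close paralogs, so its reads are assigned with less certainty. Chil1 lost its call without F-PRT 1, 2, 3 or 4, S-PRT 3 or Untreated 1 or 2 (adjusted p 0.0522 to 0.129). Sprr2i lost its call without F-PRT 1, 2 or 3 (adjusted p 0.0521 to 0.0592).

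Other lists moved in F-PRT skin with few or 0 single genes past the test over all genes. Of 34 oxidative phosphorylation genes 0 passed, 34 had a lower mean and 7 fell adjusted over the list alone, with a median log2 change of -0.37 (adjusted p = 1.14e-09, but adjusted p = 0.494 with an estimated correlation). The 44 cell cycle genes had a lower mean without exception, 0 passed and 0 passed adjusted over the list alone, with a median of -0.52 (adjusted p = 8.27e-09, but adjusted p = 0.633 with an estimated correlation). Mki67, a marker of dividing cells, was at 85.1 ± 13.6 CPM against 154 ± 24.3 CPM (log2 -0.86, SE 0.31, adjusted p = 0.215). Interferon response genes had a median of 0.62 with 0 of 43 past the test (adjusted p = 1.05e-07, but adjusted p = 0.633 with an estimated correlation), and Ifit3, an antiviral effector, was at 8.1 ± 0.59 against 3.27 ± 0.86 CPM (adjusted p = 0.087). Collagen and dermal matrix (29 of 29 positive, median 0.69), endothelial (25 of 25 positive, median 0.85) and macrophage and monocyte (24 of 25 positive, median 0.76) lists passed with 0 single genes past the test. These 3 lists shared an adjusted p = 0.633 with an estimated correlation. Marrow stroma genes (4 of 16 rose, 6 adjusted over the list alone, median 0.59) and melanocyte genes (0 of 12 passed, 4 rose adjusted over the list alone, median 0.75) passed, each at adjusted p = 0.494 with an estimated correlation. DNA repair genes passed with 1 of 35 falling and a median of -0.23 (adjusted p = 0.00281, but adjusted p = 0.677 with an estimated correlation). Keratinocyte differentiation did not pass (adjusted p = 0.109), yet Flg, the filaggrin gene, rose 2.62-fold from 409 ± 119 to 1070 ± 79.2 CPM (adjusted p = 0.0078). That list did pass as higher without F-PRT 1 or without Untreated 1 (adjusted p 0.000346 to 0.0476).

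Over all 19038 genes tested in skin, 191 rose and 264 fell after F-PRT, 455 in total (edgeR), 2835 had an unadjusted p under 0.05, and 118 rose and 149 fell by at least 2-fold. Of the 39 lists 22 passed (camera, which ranks a list against all other genes with a preset correlation of 0.01), and p53 targets alone passed once the correlation within the list was estimated from the libraries. By fry, which asks whether the genes of a list move on balance 1 way and not how they rank against others, 4 lists passed. The median, the mean and the test differed in sign for apoptosis and osteoclast, neither of which passed. The count fell to 219, 258, 216 or 229 without F-PRT 1, 2, 3 or 4, and to 242 without Untreated 2. It rose to 1477 without S-PRT 4, whose spread enters the fit, to 1215 with only the 8 libraries compared, to 940 with DESeq2, to 2623 with voom and to 2704 without S-PRT 4 and Untreated 1. Rises came to outnumber falls without Untreated 1 (254 against 238), with voom (1314 against 1309) and without S-PRT 4 and Untreated 1 (1580 against 1124). Without S-PRT 4 the cell cycle, interferon, endothelial and oxidative phosphorylation lists gained passing genes, among them Mki67 (adjusted p = 0.00975), Bub1 (0.0205), Bub1b (0.0101) and Ndc80 (0.0141). The others were Ifit1 (0.0196), Ifit2 (0.00361), Ifit3 (0.00553), Mmrn2 (0.00259), Robo4 (0.00462), Atp5j (0.0267), Cox7b (0.0291) and Cyc1 (0.0442), and in the collagen list Sparc (0.0426).

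**Figure D1:**
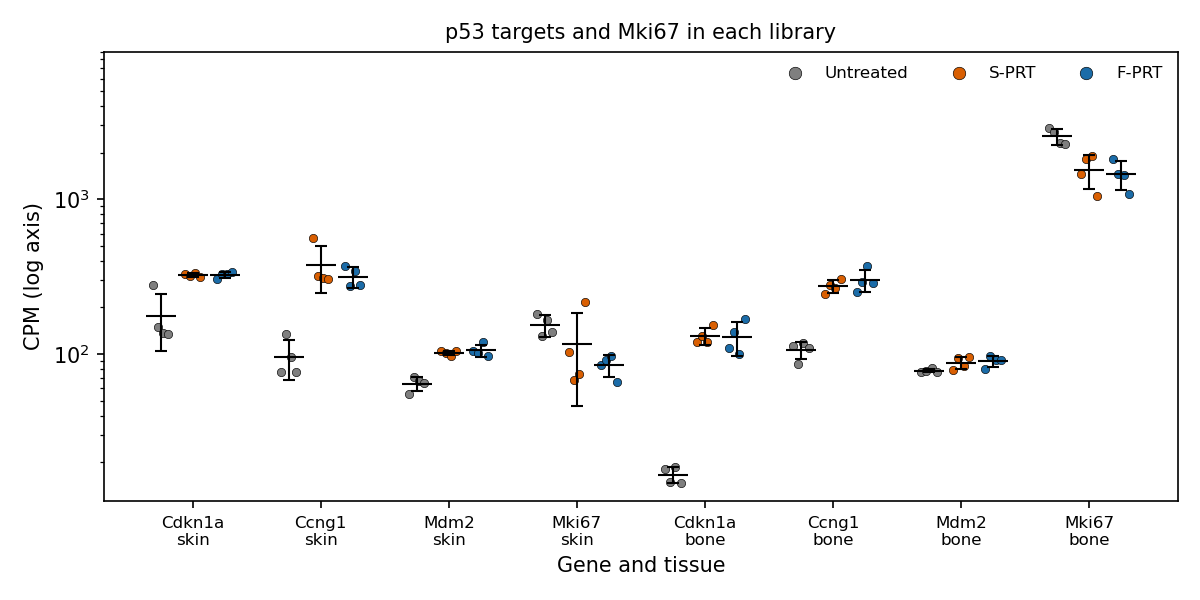
Each point shows the level of a gene in 1 library (CPM, log axis), by gene and tissue, coloured by treatment, with bars for mean and SD (n = 4). Cdkn1a and Ccng1 stand higher in both irradiated groups than in the untreated group of each tissue.

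Skin after S-PRT was set against untreated skin to ask what standard irradiation changed there. Of 30 p53 targets 24 rose, 0 fell and 6 did not pass, and 26 rose adjusted over the list alone, with a median log2 change of 1.15 (adjusted p = 1.97e-52, and adjusted p = 0.000949 with an estimated correlation). Trp53inp1 rose 4.81-fold to 348 ± 63.2 CPM (log2 2.27, SE 0.16, adjusted p = 1.03e-05), Dcxr rose 6.57-fold and Zmat3 rose 2.65-fold (each adjusted p = 2.72e-05). Ccng1 rose 3.91-fold (adjusted p = 0.000626) and Mdm2 1.58-fold (adjusted p = 0.00254). Cdkn1a was at 324 ± 10.1 CPM, 1.85-fold over Untreated (adjusted p = 0.0277), a call lost without F-PRT 1, S-PRT 1, 2 or 3, or Untreated 2, 3 or 4 (adjusted p 0.0549 to 0.113), with the muscle covariate (adjusted p = 0.0538) and with the 8 libraries compared (adjusted p = 0.0918).

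Of 28 skin lipid genes 20 fell after S-PRT, 0 rose and 8 did not pass, and 21 fell adjusted over the list alone, with a median of -1.32 (adjusted p = 2.65e-32, but adjusted p = 0.0826 with an estimated correlation). Idi1 fell to 0.297-fold (101 ± 24.7 CPM, adjusted p = 0.000101) and Hmgcs1 to 0.478-fold (adjusted p = 0.000405). Wound and stress keratinocyte genes fell in 11 of 29 cases, with 0 rising, 18 not passing and 18 falling adjusted over the list alone, at a median of -1.29 (adjusted p = 2.07e-14, but adjusted p = 0.0826 with an estimated correlation). Examples were Fabp5 (0.312-fold, adjusted p = 0.00102), Krt16 (0.409-fold, adjusted p = 0.00644) and Slpi, a protease inhibitor of wounded epidermis (0.283-fold, adjusted p = 0.0109). Among all genes under the naming rule, Ms4a10 (5.61 ± 1.81 CPM, fitted 87.5-fold), Anks1b (39.1-fold), Gapdhs (20.5-fold), Gria3 (54.5 ± 9.79 CPM, 19.1-fold, adjusted p = 3.45e-08) and Krt7 (17.2-fold) rose most. The largest falls were in Cyp2g1 (0.035-fold, log2 -4.84, SE 0.55, adjusted p = 0.000367), Akr1c18 (0.0837-fold), Serpina3b, a serine protease inhibitor (668 ± 42.9 to 67 ± 51.7 CPM), Sprr2i (0.103-fold), Scd3, a fatty acid desaturase (0.107-fold, adjusted p = 0.0275), and Hsd3b6, a steroid dehydrogenase (0.128-fold). Scd3 lost its call without F-PRT 1, S-PRT 1 or 3 or Untreated 2 or 3 (adjusted p 0.0504 to 0.0819) and with the 8 libraries compared (adjusted p = 0.117).

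Hair follicle genes passed as a list in S-PRT skin, with 1 of 25 rising, 11 rising adjusted over the list alone and a median of 0.88 (adjusted p = 0.000718, but adjusted p = 0.513 with an estimated correlation). On leaving out each library this median ran from 0.85 (without S-PRT 1) to 5.42 (without Untreated 3). The filter on low counts was rerun in each fit, so the measured members could differ. This range therefore does not show the weight of a library alone. Krt26, a keratin of the hair inner root sheath, was at 8.57 ± 14 CPM against 0.13 ± 0.08 CPM (63.2-fold, log2 5.98, SE 1.3, adjusted p = 0.0211), of which S-PRT 1 held 29.4 CPM. That call was lost without Untreated 2, 3 or 4 (adjusted p 0.0594 to 0.0795), with voom (0.147), with the muscle covariate (0.0663) and with the 8 libraries compared (0.0951). Tchh, trichohyalin, held 359 CPM in S-PRT 1 and 8.1 to 53.2 CPM in the other 3. Skeletal muscle genes were positive in 29 of 29 cases with 0 past the test and a median of 1.66 (adjusted p = 0.00077, but adjusted p = 0.663 with an estimated correlation). This list call was lost without S-PRT 1, where the median turned to -0.22 (adjusted p = 0.307), or without Untreated 4 (median 1.25, adjusted p = 0.0999). S-PRT 1 stood at 9.15 mean log2 CPM of muscle genes and Untreated 4 at -0.71. Interferon genes (median 0.61, 0 of 43 passing, adjusted p = 0.513 with an estimated correlation), cell cycle genes (median -0.38, 0 of 44 passing, adjusted p = 0.599 with an estimated correlation) and oxidative phosphorylation genes (median -0.28, 2 of 34 falling, 7 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation) passed as lists. Of the oxidative phosphorylation genes, Cox7b fell to 0.676-fold (adjusted p = 0.0163), a call lost without Untreated 2 (0.0629) or 3 (0.0512). Atp5j fell to 0.736-fold (adjusted p = 0.0409), a call lost without F-PRT 1, 2 or 3, S-PRT 1, 2 or 3 or Untreated 2, 3 or 4 (0.0546 to 0.104), without a filter on low counts (0.134), with the muscle covariate (0.0834) and with the 8 libraries compared (0.17). TGF-beta response genes passed with 3 of 29 rising, 5 adjusted over the list alone and a median of 0.40 (adjusted p = 0.00144, but adjusted p = 0.513 with an estimated correlation). T cell and NK cell genes passed with 0 of 24 past the test and a median of -0.71 (adjusted p = 0.00121), a call that ended at adjusted p = 0.513 with an estimated correlation and at 0.301 without S-PRT 4 and Untreated 1.

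In skin S-PRT 4 the endothelial list mean was 0.21 log2 CPM against 4.12 to 4.34 in the other S-PRT libraries, the collagen list 4.24 against 6.81 to 7.04, and the basal keratinocyte list 9.51 against 8.10 to 8.29. Pecam1, an endothelial adhesion molecule, was at 1.64 CPM there against 62.7 to 66.8 CPM. The endothelial list did not pass in S-PRT against Untreated (median 0.44, adjusted p = 0.266) and passed without S-PRT 4 (adjusted p = 1.24e-11). Dermal collagen passed with 1 of 29 rising and a median of 0.58 (adjusted p = 0.00259, but adjusted p = 0.663 with an estimated correlation) and lost its call without S-PRT 2 or Untreated 3 (adjusted p 0.0972 to 0.102).

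Over the 19038 genes tested, 348 rose and 479 fell after S-PRT, 827 in total (edgeR), 3202 had an unadjusted p under 0.05, and 163 rose and 251 fell by at least 2-fold. Of 39 lists 25 passed, and p53 targets alone passed with an estimated correlation; the median, the mean and the test differed in sign for apoptosis, haematopoietic stem, mast cell and osteoclast lists, none of which passed. The count was 538 without S-PRT 1, 2270 without S-PRT 4, 1279 without Untreated 1, 452 without Untreated 2 and 539 without Untreated 3. It was 305 with the 8 libraries compared, 1487 with DESeq2, 3102 with voom and 4509 without S-PRT 4 and Untreated 1. Rises came to outnumber falls without S-PRT 4 (1256 against 1014), without Untreated 1 (643 against 636), with voom (1577 against 1525) and without both of these libraries (2495 against 2014). Without S-PRT 4 more members of the interferon and cell cycle lists passed, among them Ifit2 (adjusted p = 0.000754), Ifit3 (0.00266), Tap1 (0.0399), Mki67 (0.00884), Bub1 (0.00848), Cdk1 (0.00425) and Ccna2 (0.0136), and Tap1 also passed without Untreated 1 (0.028).

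**Figure D2:**
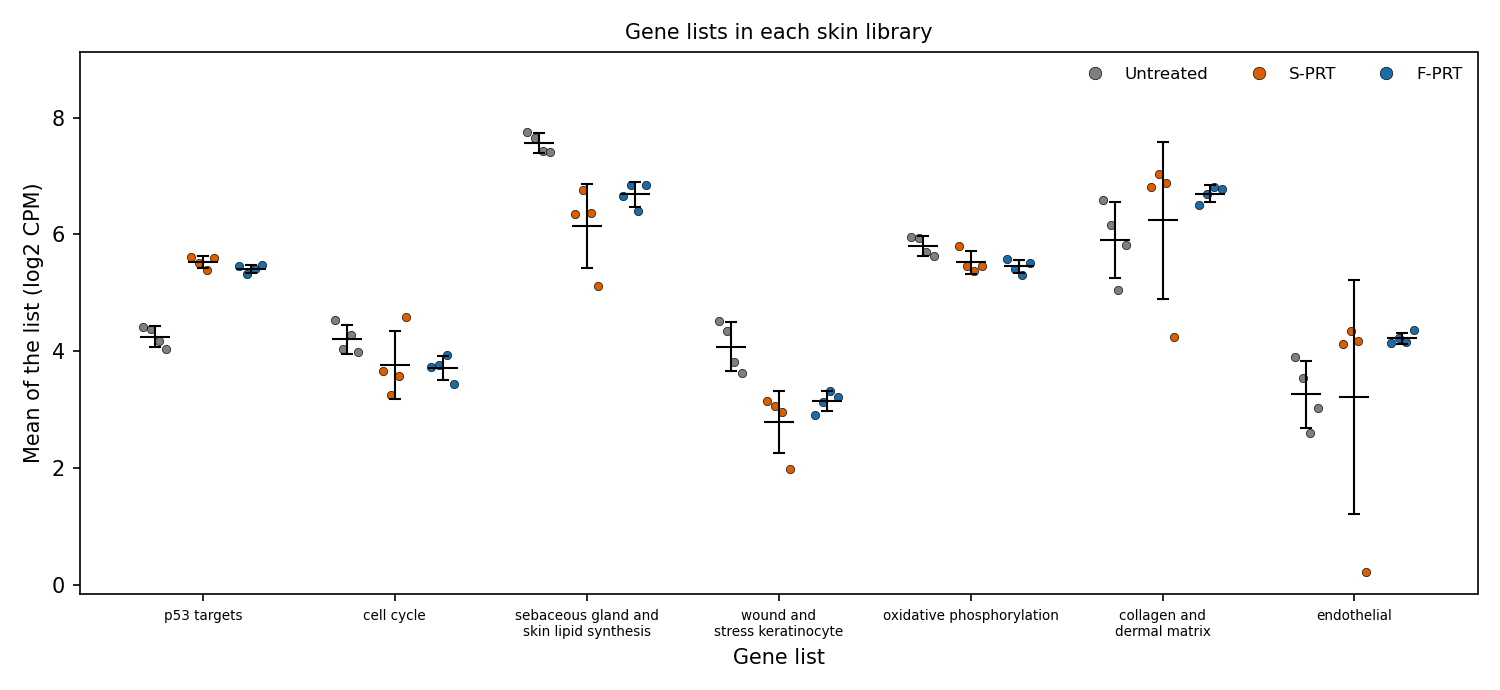
Each point shows the mean of a gene list in 1 skin library (log2 CPM), coloured by treatment, with bars for mean and SD (n = 4). S-PRT 4 stands far below the other libraries for endothelial and collagen genes.

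Skin after F-PRT was set against skin after S-PRT to ask where the beams differed, and 0 of 19038 genes passed (edgeR), with 522 at an unadjusted p under 0.05. By DESeq2 2 passed, Nnat (adjusted p = 4.5e-06) and Hcar1 (0.000117), and by voom 0. The adipocyte list was higher after F-PRT: 18 of 20 genes were positive, 8 rose adjusted over the list alone and 0 over all genes, with a median log2 difference of 0.52 (adjusted p = 1.21e-21, but adjusted p = 0.355 with an estimated correlation and 0.605 by fry). Nnat (ENSMUSG00000067786, chromosome 2, 157560078 to 157562522), neuronatin, was at 49.1 ± 11.5 against 24.1 ± 1.53 CPM (2.04-fold, log2 1.03, SE 0.15, adjusted p = 0.237), and it passed without F-PRT 3 (adjusted p = 0.0201). Fabp4, the fatty acid binding protein of fat cells, was at 237 ± 57 against 128 ± 41.1 CPM, and Adrb3, the adrenergic receptor of fat cells, at 12.9 ± 2.02 against 7.35 ± 1.92 CPM (each adjusted p = 0.999). Hcar1, the lactate receptor of fat cells (2.25-fold, adjusted p = 0.498), Slc5a3, an inositol transporter (1.56-fold), and Tmem28 (0.293-fold) completed the 5 genes of smallest p (adjusted p = 0.999 for the last pair). Keratinocyte differentiation genes were higher in 38 of 39 cases with 0 past the test and a median of 0.37 (adjusted p = 9.41e-13, but adjusted p = 0.672 with an estimated correlation); Flg stood at 1070 ± 79.2 against 702 ± 188 CPM. Skin lipid genes were positive in 22 of 28 cases with a median of 0.40 (adjusted p = 5.88e-10, but adjusted p = 0.672 with an estimated correlation).

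Hair follicle genes were lower after F-PRT than after S-PRT in 23 of 25 cases, 12 adjusted over the list alone and 0 over all genes, with a median of -1.03 (adjusted p = 1.14e-13, but adjusted p = 0.583 with an estimated correlation). On leaving out each library this median ran from -3.77 (without S-PRT 2) to -0.76 (without S-PRT 1). The hair list mean was 4.97 in S-PRT 1 and 3.87 in S-PRT 4, against 1.72 and 2.16 in the other S-PRT libraries. The endothelial (median 0.39), basal keratinocyte (median -0.51) and p53 target (median -0.12) lists passed at adjusted p = 2.88e-08, 6.18e-07 and 0.00812, with 0 genes past the test. With an estimated correlation their adjusted p were 0.701, 0.672 and 0.672. Without S-PRT 4, the library poor in vessel and dermis genes, these 3 calls were lost at adjusted p = 0.995, 0.696 and 0.282. Skeletal muscle genes were negative in 29 of 29 cases (median -1.49, adjusted p = 5.58e-05, but adjusted p = 0.728 with an estimated correlation), and without S-PRT 1 the list did not pass (adjusted p = 0.6) and its median turned to 0.41. The cell cycle list, which had not passed (adjusted p = 0.176), passed as higher without S-PRT 4 (median 0.24, adjusted p = 1.58e-08). It passed as lower without F-PRT 3 or S-PRT 1, 2 or 3 (medians -0.30 to -0.22, adjusted p 6.79e-05 to 0.032). The interferon list (adjusted p = 0.982) passed as lower without S-PRT 4 (median -0.22, adjusted p = 1.89e-09) and as higher without S-PRT 3 (median 0.12, adjusted p = 0.00682).

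Of the 39 lists 18 passed between the beams in skin and 0 passed with an estimated correlation or with fry. The median, mean and test differed in sign for macrophage, apoptosis, plasma cell, erythroid and interferon lists, none of which passed. In simulated data of this design edgeR recovered 43.3% of genes changed 2-fold and 92.4% of genes changed 4-fold between F-PRT and S-PRT skin, so that smaller differences could pass unseen at this depth and spread.

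Bone after F-PRT was set against untreated bone to ask what FLASH irradiation changed there, and genes of blood-forming lineages fell. Megakaryocyte and platelet genes fell in 19 of 22 cases, with 0 rising and 3 not passing (19 fell adjusted over the list alone), at a median log2 change of -2.29 (adjusted p = 3.85e-65, and adjusted p = 0.00034 with an estimated correlation). Ppbp, a platelet chemokine, fell from 662 ± 53.1 to 84.1 ± 11.4 CPM (adjusted p = 1.22e-08), and Rab27b, which acts in granule secretion, to 0.247-fold (adjusted p = 1.49e-08). Neutrophil and granulocyte precursor genes fell in 25 of 27 cases, 25 adjusted over the list alone, at a median of -3.55 (adjusted p = 5e-24, but adjusted p = 0.245 with an estimated correlation). Camp, the cathelicidin of neutrophil granules, fell from 291 ± 138 to 6.77 ± 1.09 CPM (0.0233-fold, adjusted p = 2.61e-06), Ly6g, a neutrophil surface marker, to 0.021-fold and Padi4, an enzyme of neutrophil chromatin, to 0.0855-fold. Erythroid genes fell in 19 of 28 cases, 22 adjusted over the list alone, at a median of -0.83 (adjusted p = 1.99e-11, but adjusted p = 0.314 with an estimated correlation). Alas2, which starts haem synthesis in red cells, fell to 0.34-fold (adjusted p = 1.74e-05), and the near-identical globin genes Hbb-bs and Hbb-bt, between which reads are divided with less certainty, fell to 0.271-fold and 0.301-fold.

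Cell cycle and B cell genes were lower as lists in F-PRT bone. Cell cycle genes fell in 30 of 44 cases, 31 adjusted over the list alone, at a median of -0.63 (adjusted p = 1.46e-08, but adjusted p = 0.459 with an estimated correlation). Foxm1, a driver of mitotic genes, fell from 89.1 ± 9.3 to 47.7 ± 4.45 CPM (adjusted p = 0.000221), Racgap1 to 0.565-fold and Cenpa, the centromeric histone, to 0.532-fold. Mki67 fell from 2550 ± 301 to 1450 ± 307 CPM (0.568-fold, log2 -0.82, adjusted p = 0.00682). The call ended with the keratinocyte covariate (log2 -0.48, adjusted p = 0.195) and without F-PRT 2, F-PRT 3 and Untreated 1 (log2 -0.74, adjusted p = 0.0647). B cell genes fell in 13 of 25 cases and rose in 1, at a median of -0.73 (adjusted p = 9.65e-05, but adjusted p = 0.467 with an estimated correlation). DNA repair genes fell in 12 of 35 cases and rose in 1 (median -0.25, adjusted p = 0.0185, but adjusted p = 0.546 with an estimated correlation), and this call ended with the keratinocyte covariate (adjusted p = 0.463). The largest falls under the naming rule were in the neutrophil genes Ltf, lactoferrin (1410 ± 638 to 25 ± 6.37 CPM, 0.0177-fold, log2 -5.82, SE 0.51, adjusted p = 3.63e-06), Olfm4 (0.0222-fold), Ngp (0.0245-fold), Camp and Ly6g, together with the long noncoding RNA AC025794.1 (0.0224-fold). Of 7 measured wound and stress genes 4 fell and 1 rose, at a median of -2.09 (adjusted p = 0.0567, and 0.459 with an estimated correlation). That list passed on leaving out any library but Untreated 3 or 4 (adjusted p 4.05e-05 to 0.0467). It shares S100a8 and S100a9 with the neutrophil list, so its fall need not be one of keratinocytes. Haematopoietic stem and progenitor genes fell in 7 of 22 cases and rose in 2 (adjusted p = 0.051, and 0.314 with an estimated correlation). That list passed without F-PRT 2, S-PRT 1, 3 or 4 or Untreated 1 (adjusted p 0.023 to 0.0444).

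Against these falls p53 targets, interferon genes and stromal genes rose in F-PRT bone. CPM values are relative to the other genes of a library. For the cell type lists here and below, a gain of those cells and a larger share left by the falls cannot be told apart. Of 29 p53 targets 21 rose, 2 fell and 6 did not pass, 23 rising adjusted over the list alone, at a median of 0.93 (adjusted p = 6.53e-18, and adjusted p = 0.044 with an estimated correlation). Cdkn1a rose 7.74-fold from 16.7 ± 2.05 to 129 ± 31.3 CPM (log2 2.95, SE 0.17, adjusted p = 1.25e-07), Zmat3 4.66-fold, Ephx1, an epoxide hydrolase, 4.51-fold and Ccng1 2.81-fold. Mdm2 was at 90.2 ± 7.21 against 78.3 ± 1.75 CPM (adjusted p = 0.0922) and passed without F-PRT 1 (adjusted p = 0.0491) and with DESeq2 (adjusted p = 0.0474). Interferon response genes rose in 35 of 43 cases and fell in 1, 37 rising adjusted over the list alone, at a median of 1.14 (adjusted p = 2.16e-24, but adjusted p = 0.231 with an estimated correlation). Ifi44, an interferon-induced gene, rose 4.7-fold from 4.95 ± 0.78 to 23.5 ± 4.97 CPM (adjusted p = 1.5e-06), Gbp6, a guanylate-binding protein, 4.27-fold and Ifit2 3.11-fold. T cell and NK cell genes rose in 24 of 30 cases and fell in 1 (median 1.23, adjusted p = 1.23e-11, but adjusted p = 0.245 with an estimated correlation), among them Eomes, a T-box factor of NK and memory T cells (3.26-fold), Cd28, a costimulatory receptor (2.25-fold), and Zap70, a T cell receptor kinase (2.49-fold). Marrow stroma genes rose in 15 of 17 cases, 16 adjusted over the list alone (median 0.89, adjusted p = 6.19e-15, but adjusted p = 0.0741 with an estimated correlation). Il7, a lymphoid growth factor, rose 4.26-fold, Lpl, lipoprotein lipase, 3.32-fold and Gas6, a ligand of TAM receptors, 3.98-fold. Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068), a B cell attracting chemokine, rose from 0.95 ± 0.34 to 40.7 ± 13.5 CPM (42.2-fold, adjusted p = 2e-07). Eda2r, a receptor of the TNF family and p53 target (10.9-fold), Xcr1, a receptor of cross-presenting dendritic cells (9.12-fold), Cma1, a mast cell chymase (8.67-fold), and Sfrp2, a secreted Wnt modulator (8.17-fold), also led the rises.

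Further lists rose in F-PRT bone, each without a call at an estimated correlation. Inflammatory cytokines (16 of 27 rose, 4 fell, median 1.08, adjusted p = 0.0945 with an estimated correlation), TGF-beta response (20 of 30 rose, 2 fell, median 0.66, adjusted p = 0.245), adipocyte (13 of 20, median 0.97, adjusted p = 0.245) and dendritic cell genes (12 of 19 rose, 1 fell, median 1.02, adjusted p = 0.245) are given with that estimate. On the same footing were collagen (18 of 29, median 0.60, adjusted p = 0.314), endothelial (15 of 26 rose, 2 fell, median 0.76, adjusted p = 0.314), smooth muscle and pericyte (10 of 16, median 0.95, adjusted p = 0.245), and macrophage genes (16 of 25 rose, 4 fell, median 1.15, adjusted p = 0.44). Bone cell lists rose too: osteoblast (14 of 29, median 0.57, adjusted p = 0.467 with an estimated correlation), osteoclast (18 of 25 rose, 2 fell, median 0.73, adjusted p = 0.472) and osteocyte (5 of 15, median 0.51, adjusted p = 0.459). Chondrocyte and growth plate genes (4 of 31 rose, 1 fell, median 0.68, adjusted p = 0.0486, but 0.682 with an estimated correlation) lost their call without F-PRT 1, 2 or 4, S-PRT 2 or Untreated 2, 3 or 4 (adjusted p 0.0602 to 0.181). Nerve and Schwann cell (6 of 16 rose, 1 fell, adjusted p = 0.323), senescence and secretory (10 of 21 rose, 4 fell, adjusted p = 0.245) and immediate early genes (10 of 25 rose, 2 fell, adjusted p = 0.459) also passed only with the preset correlation. The osteocyte and nerve calls ended with the keratinocyte covariate (adjusted p = 0.114 and 0.106). NRF2 antioxidant genes (10 of 24 rose, 4 fell, median 0.38, adjusted p = 0.0273, but 0.459 with an estimated correlation) lost their call without Untreated 1 (adjusted p = 0.126). Ctsk, the collagen-cleaving protease of osteoclasts, rose 1.87-fold (log2 0.90, adjusted p = 0.00912; log2 0.66 and 0.143 with the keratinocyte covariate). Col1a1, the main bone collagen, was at 23200 ± 6350 against 14200 ± 3630 CPM (1.63-fold, adjusted p = 0.0361), a call lost without F-PRT 1, 2 or 4 or Untreated 2, 3 or 4 (adjusted p 0.0606 to 0.104), with the 8 libraries compared (log2 0.73, 0.0762) and with the keratinocyte covariate (log2 0.53, 0.282). Apoptosis (adjusted p = 0.212), hypoxia (0.618), mast cell (0.774), plasma cell (0.617), melanocyte (0.524) and hair follicle genes (0.292) did not pass.

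Genes of skin keratinocytes also stood higher in F-PRT bone, unevenly over its libraries. If they came from skin RNA, 22 such genes put its share at 1.14% in F-PRT 2, 0.397% in F-PRT 4 and 0.178% in F-PRT 3. F-PRT 1 held 0.00817% and S-PRT 4 0.181%. An effect of F-PRT on these genes and skin cells in the bone samples were not told apart. Krt10, a keratin of the upper epidermis, was at 24.5 ± 28.1 against 0.23 ± 0.17 CPM (96.1-fold, log2 6.59, SE 1.41, adjusted p = 0.00314), with 64.5 CPM in F-PRT 2, 22 in F-PRT 4, 11.1 in F-PRT 3 and 0.41 in F-PRT 1. Keratinocyte differentiation genes rose in 15 of 20 measured cases at a median of 4.31 (adjusted p = 0.00196, but 0.506 with an estimated correlation). The Krt10 call ended with voom (log2 5.13, adjusted p = 0.238) and with the keratinocyte covariate (log2 1.74, 0.0831). The small nuclear RNA 7SK took 3.86% ± 0.55 of counts in untreated bone, 2.05% ± 0.24 after F-PRT and 2.35% ± 0.085 after S-PRT.

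Over the 18848 genes tested in bone, 2925 rose and 3236 fell after F-PRT (edgeR), 6161 in total, with 8054 at an unadjusted p under 0.05, and 886 rose and 1116 fell by at least 2-fold. Of 39 lists 29 passed, of which megakaryocyte and p53 targets also passed with an estimated correlation. The signs of median, mean and test differed for plasma and mast cell lists, which did not pass. The count ran from 4803 to 6727 on leaving out single libraries and fell to 2660 with the keratinocyte covariate. Rises came to outnumber falls without a filter on low counts (3179 against 2336), without Untreated 1 (3542 against 3185) and without F-PRT 2, F-PRT 3 and Untreated 1 (2419 against 2250).

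**Figure D3:**
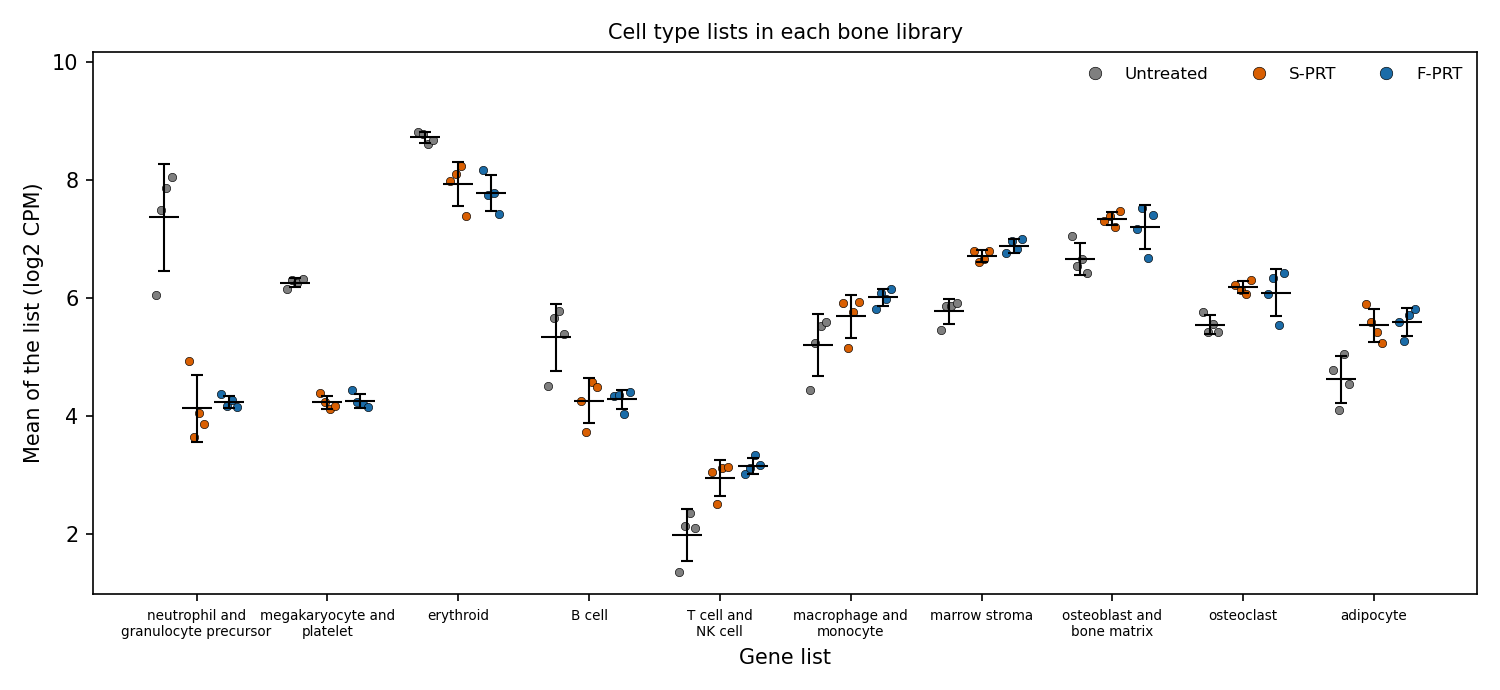
Each point shows the mean of a cell type list in 1 bone library (log2 CPM), coloured by treatment, with bars for mean and SD (n = 4). Neutrophil, megakaryocyte and erythroid lists stand lower and the marrow stroma list higher in both irradiated groups.

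Bone after S-PRT was set against untreated bone. Megakaryocyte and platelet genes fell in 19 of 22 cases and 0 rose, at a median of -2.37 (adjusted p = 1.79e-74, and 0.000234 with an estimated correlation), with Ppbp at 0.123-fold and Rab27b at 0.236-fold. Neutrophil genes fell in 25 of 27 cases (median -3.69, adjusted p = 7.14e-28, but 0.219 with an estimated correlation), with Camp at 0.0258-fold, Padi4 at 0.0732-fold and Ly6g at 0.0221-fold. Erythroid genes fell in 18 of 28 cases (median -0.70, adjusted p = 0.431 with an estimated correlation), with Alas2 at 0.394-fold, and cell cycle genes fell in 26 of 44 (median -0.58, adjusted p = 0.481 with an estimated correlation), with Foxm1 at 0.517-fold, Bub1b at 0.615-fold and Mki67 at 0.609-fold (adjusted p = 0.016). Rag1 (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501), the recombinase of developing lymphocytes, fell from 63.1 ± 17.1 to 1.36 ± 0.22 CPM (0.0217-fold, log2 -5.53, SE 0.29, adjusted p = 4.8e-08). Olfm4 (0.0181-fold), Ceacam10 (0.0209-fold) and Ltf (0.0222-fold) stood with it among the largest falls. B cell genes fell in 12 of 25 cases and rose in 2 (median -0.51, adjusted p = 0.000222, but 0.481 with an estimated correlation). Haematopoietic stem and progenitor genes fell in 8 of 22 and rose in 2 (median -0.34, adjusted p = 0.00949, but 0.313 with an estimated correlation). Of 7 measured wound and stress genes 4 fell and 1 rose (adjusted p = 0.0115, but 0.355 with an estimated correlation).

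Of 29 p53 targets 21 rose, 2 fell and 6 did not pass in S-PRT bone, 22 rising adjusted over the list alone, at a median of 0.83 (adjusted p = 6.72e-18, and adjusted p = 0.0466 with an estimated correlation). Cdkn1a rose 7.83-fold to 130 ± 16 CPM (log2 2.97, SE 0.17, adjusted p = 1.13e-07), Zmat3 4.41-fold and Ephx1 4.53-fold. Ccng1 rose 2.56-fold from 107 ± 13.9 to 274 ± 25.6 CPM (adjusted p = 1.01e-05). Cxcl13 rose 38.7-fold to 37.3 ± 10.5 CPM, Eda2r 10.8-fold, Sfrp2 8.27-fold, Zfp365, a p53-induced gene of DNA damage, 7.41-fold and Xcr1 6.65-fold. Interferon genes rose in 23 of 43 cases and fell in 2, 29 rising adjusted over the list alone, at a median of 0.53 (adjusted p = 1.87e-07, but 0.451 with an estimated correlation). Marrow stroma genes rose in 14 of 17 and fell in 1 (median 0.92, adjusted p = 0.123 with an estimated correlation), T cell and NK cell genes rose in 21 of 30 and fell in 1 (median 1.11, adjusted p = 0.355 with an estimated correlation) and TGF-beta response genes rose in 20 of 30 and fell in 2 (median 0.66, adjusted p = 0.33 with an estimated correlation). Examples were Il7 (3.27-fold), Cd8a, a cytotoxic T cell coreceptor (2.69-fold), Thy1 (2.25-fold), Col8a1, a short-chain collagen (5.1-fold), Ltbp2 (2.96-fold) and Tgfb3 (1.78-fold). Chondrocyte and growth plate genes rose in 11 of 31 and fell in 1 (median 1.01, adjusted p = 5.55e-05, but 0.481 with an estimated correlation). Col2a1, the cartilage collagen, was at 922 ± 95.6 against 417 ± 280 CPM (adjusted p = 0.105). It passed without F-PRT 3 (adjusted p = 0.0206), without Untreated 1 (0.0111), without F-PRT 2, F-PRT 3 and Untreated 1 together (1.54e-05), with voom (0.0188), without a filter on low counts (0.00821) and with the 8 libraries compared (0.0361). Col1a1 rose 1.82-fold (adjusted p = 0.0159) and Ctsk 1.82-fold (adjusted p = 0.0129). The limit on cell type lists given for F-PRT bone holds here too.

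Over the 18848 genes tested, 2512 rose and 2868 fell after S-PRT (edgeR), 5380 in total, with 7407 at an unadjusted p under 0.05, and 673 rose and 960 fell by at least 2-fold. Of 39 lists 29 passed, of which megakaryocyte and p53 targets also passed with an estimated correlation, and the signs of median, mean and test differed for plasma and mast cell lists, which did not pass. Rises came to outnumber falls without a filter on low counts (2765 against 2048) and without Untreated 1 (3231 against 2927). Keratinocyte differentiation genes did not pass after S-PRT (median 2.08, adjusted p = 0.161), though they did without F-PRT 1 or S-PRT 2 (adjusted p 0.0446 to 0.0471).

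Bone after F-PRT was set against bone after S-PRT to ask where the beams differed, and interferon response genes were higher after F-PRT. All 43 measured members had a higher mean, 0 passed over all genes and 33 rose adjusted over the list alone, at a median log2 difference of 0.57 (adjusted p = 1.79e-77, but adjusted p = 0.0525 with an estimated correlation and 0.143 by fry). The list mean was 5.61 to 5.96 log2 CPM in the 4 F-PRT libraries, 4.83 to 5.31 in the 4 S-PRT libraries and 4.14 to 4.89 in the 4 untreated libraries. Ifi44 was at 23.5 ± 4.97 CPM after F-PRT and 11.1 ± 1.6 after S-PRT (2.11-fold, adjusted p = 0.123), Ifit2 at 62.2 ± 9.91 and 31.1 ± 6.78 CPM (2-fold, adjusted p = 0.123) and Gbp6 at 44.2 ± 10.7 and 25.7 ± 3.53 CPM (adjusted p = 0.611). The single gene past the test was Slfn4 (ENSMUSG00000000204, chromosome 11, 83175186 to 83190216), a myeloid gene of the interferon-inducible Schlafen family, at 55 ± 7.92 CPM after F-PRT, 27.3 ± 4.13 CPM after S-PRT and 158 ± 13.5 CPM untreated (2.02-fold between beams, log2 1.01, SE 0.13, adjusted p = 0.043). Ddx60 (1.65-fold) and Ifih1, a sensor of viral RNA (1.37-fold), followed by p (each adjusted p = 0.611). With DESeq2 Ifi44 (adjusted p = 1.36e-05), Ifit2 (1.4e-05), Ddx60 (0.005), Ifih1 (0.00516) and Gbp6 (0.00995) passed as well. Without a filter on low counts Ifi44 and Ifit2 passed (each adjusted p = 0.00466). Slfn4 lost its call without F-PRT 1, 2 or 4, S-PRT 1, 2, 3 or 4, or Untreated 2, 3 or 4 (adjusted p 0.0693 to 0.277). It also lost it with the muscle covariate (log2 1.01, adjusted p = 0.0668), the 8 libraries compared (log2 1.01, 0.129), the keratinocyte covariate (log2 0.97, 0.479) and without F-PRT 2, F-PRT 3 and Untreated 1 together (log2 1.14, 0.0537). The fold thus stayed about as large in these fits.

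Keratinocyte differentiation genes were also higher in F-PRT than in S-PRT bone, in 19 of 20 cases and in 14 adjusted over the list alone, at a median of 2.42 (adjusted p = 9.39e-14, but adjusted p = 0.547 with an estimated correlation). Flg stood at 23.2 CPM in F-PRT 2, 6.91 in F-PRT 4, 5.42 in F-PRT 3 and 0.12 in F-PRT 1, and at 0.42 to 1.83 CPM after S-PRT. Macrophage and monocyte genes were positive in 24 of 25 cases (median 0.26, adjusted p = 1.82e-07, but adjusted p = 0.547 with an estimated correlation), with Ly6c2, a monocyte marker, at 194 ± 24.6 against 111 ± 27.7 CPM (adjusted p = 1). Marrow stroma genes were positive in 14 of 17 (median 0.17, adjusted p = 9.22e-05, but adjusted p = 0.547 with an estimated correlation, and 0.0654 with the keratinocyte covariate). Chondrocyte genes were negative in 31 of 31 (median -0.35, adjusted p = 1.37e-09, but adjusted p = 0.547 with an estimated correlation), a call lost without F-PRT 3 (adjusted p = 0.0871). Cell cycle (adjusted p = 0.231) and p53 targets (adjusted p = 0.198) did not pass between the beams with all libraries. Both passed without F-PRT 1 or S-PRT 4, cell cycle as lower (medians -0.18 to -0.16, adjusted p 4.11e-11 to 4.93e-06) and p53 targets as higher (medians 0.08 to 0.09, adjusted p 0.00544 to 0.0395). Osteoclast genes (adjusted p = 0.121) passed as lower without F-PRT 2, F-PRT 4 or S-PRT 3 (adjusted p 0.00011 to 0.0454) and as higher without F-PRT 3 (adjusted p = 0.0216).

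In all, 1 of 18848 genes passed between the beams in bone (edgeR), 634 had an unadjusted p under 0.05, 21 passed with DESeq2, 1 with voom and 11 without a filter on low counts. Of 39 lists 15 passed and 0 passed with an estimated correlation or with fry, 25 lists passed without S-PRT 1 and 8 passed without F-PRT 2, F-PRT 3 and Untreated 1; the B cell list, which did not pass, differed in sign between median and mean. In simulated data edgeR recovered 40.3% of genes changed 1.5-fold and 68.7% of those changed 2-fold between F-PRT and S-PRT bone.

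**Figure D4:**
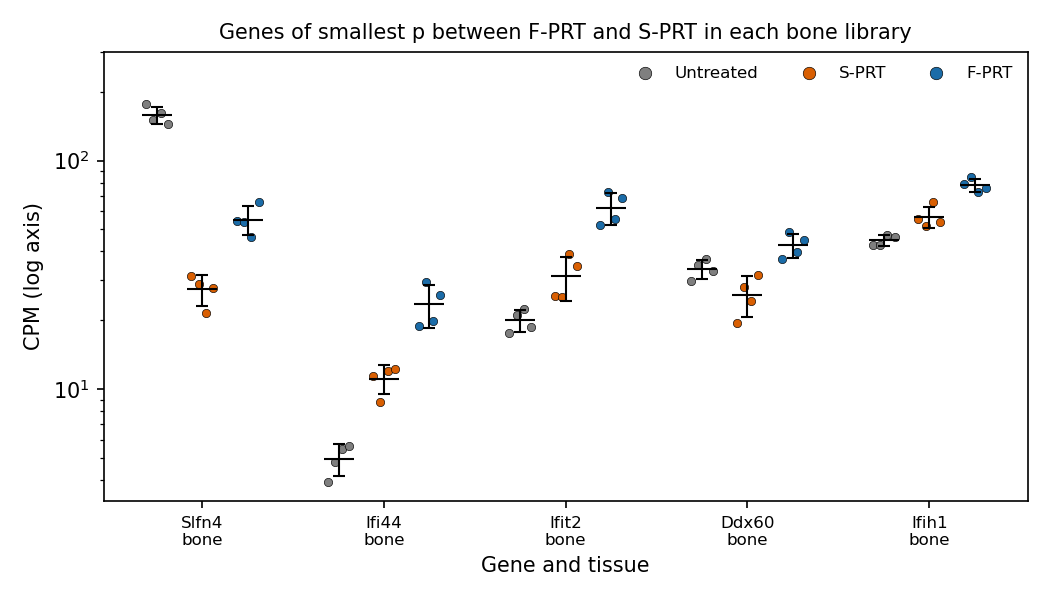
Each point shows the level of a gene in 1 bone library (CPM, log axis), coloured by treatment, with bars for mean and SD (n = 4). The genes are the 5 of smallest p between the beams, and in each the F-PRT points lie above the S-PRT points.

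Skin and bone were compared by the difference of their responses (interaction) over 20754 genes. Gria3 rose in skin and not in bone, with a difference of 4.22 for F-PRT (SE 0.25, adjusted p = 1.06e-09) and 4.24 for S-PRT (adjusted p = 9.68e-10); its untreated level was 2.85 ± 0.27 CPM in skin and 34.6 ± 1.81 CPM in bone. Mpig6b, a platelet receptor, changed by log2 -0.08 in skin and -2.79 in bone after F-PRT, a difference of 2.71 (adjusted p = 8.31e-09), and by -0.02 and -3.01 after S-PRT, a difference of 2.99 (adjusted p = 2.31e-09). Ifnlr1, the interferon lambda receptor, differed by 3.82 after F-PRT and 3.72 after S-PRT, and Syne1, a nuclear envelope protein, by 2.92 and 2.69. Adpgk, a glycolytic kinase, differed by 2.71 after F-PRT and Ppbp by 3.45 after S-PRT. Megakaryocyte genes differed as a list, with medians of 0.51 in skin and -2.27 in bone after F-PRT (adjusted p = 6.12e-28, and 4.54e-05 with an estimated correlation) and of 0.45 and -2.35 after S-PRT (adjusted p = 1.45e-31, and 2.01e-05 with an estimated correlation). The p53 target list had medians of 0.98 in skin and 0.98 in bone after F-PRT, with a difference not past the test (adjusted p = 0.794), as after S-PRT (medians 1.14 and 0.84, adjusted p = 0.0843). In the contrast of F-PRT with S-PRT its difference passed (medians -0.11 and 0.05, adjusted p = 0.00317, but adjusted p = 0.804 with an estimated correlation). Interferon genes differed between tissues in the contrast of F-PRT with S-PRT, with medians of -0.06 in skin and 0.58 in bone (adjusted p = 2.57e-16, but adjusted p = 0.804 with an estimated correlation). The sebaceous and lipid list fell in skin and not in bone after S-PRT (medians -1.31 and 0.24, adjusted p = 1.3e-18, but adjusted p = 0.146 with an estimated correlation). The response differed for 2212 genes after F-PRT (968 higher and 1244 lower in skin, 5095 at an unadjusted p under 0.05) and 1961 after S-PRT (1029 higher and 932 lower, 4660 at an unadjusted p under 0.05). Signs were opposite for 1684 and 1548, counting values near 0. For F-PRT against S-PRT 0 genes passed (edgeR, 730 at an unadjusted p under 0.05, 1 with DESeq2), and the genes of smallest p were Grhl3, H2-Q4 and Eif2ak2 (each adjusted p = 1). H2-Q4 has close paralogs among class I genes, so its reads are assigned with less certainty.

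The effects of F-PRT and S-PRT share their untreated libraries, so a correlation (r) arises even without a shared effect. Across genes, which are not independent replicates, r was 0.793 in skin (covariance 0.241) and 0.917 in bone (covariance 0.487). Simulated unchanged groups gave r = 0.507 (0.49 to 0.531 in 20 draws, covariance 0.0742) in skin and r = 0.522 (0.491 to 0.55, covariance 0.0473) in bone. With the 4 untreated libraries split 2 and 2 between the effects, r was 0.439 (0.351 to 0.534 over 6 assignments, covariance 0.182) in skin and 0.725 (0.666 to 0.749, covariance 0.437) in bone. The observed covariance exceeded the simulated by 0.167 in skin and 0.44 in bone. In skin 174 genes rose (3.49 from the product of the counts over genes tested, which leaves out the shared libraries) and 221 fell (6.64) in both. In bone 2219 rose (390) and 2512 fell (492) in both. Of genes past either test, 887 of 887 in skin and 6796 of 6810 in bone had the same sign. Simulated unchanged groups against shared controls gave 0 genes called in both in 20 draws. Relabelled real libraries gave up to 1297 calls for S-PRT in skin and 322 in bone, so this 0 is a weak benchmark. Among as many genes of smallest p, the draws had the same sign for 87.5% to 92% in skin and 79.4% to 81.4% in bone. With the controls split, 63 to 77 genes rose and 59 to 98 fell in both in skin, and 1118 to 1327 rose and 1454 to 1590 fell in bone. The same sign then held for 96.2% to 100% of genes past either test in skin and 92.1% to 98.1% in bone.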

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

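The tests of other splits of the samples, of bone RNA in skin, of genomic DNA, of reads shared between repeat models, of a mislabelled library, of less dermis and of depth were chosen only after the result was seen. A library is named below where its gap to the nearest of its group of 4 exceeded the 95% critical value of the Dixon test, which chance gives in about 1 in 20 groups. Among list means 23 of 234 groups met this (9.83%), of which 15 lay in skin S-PRT 4, among library measures 11 of 48 (22.9%), among panel genes 2 of 45 (4.44%) and among named genes 32 of 376 (8.51%).

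Skin S-PRT 4 stood apart from the other 3 S-PRT libraries (in brackets) in 15 list means (log2 CPM). It was lower for endothelial 0.21 (4.12 to 4.34), collagen 4.24 (6.81 to 7.04), macrophage 2.43 (4.48 to 4.56), mast cell -0.29 (3.18 to 3.86), dendritic cell 1.21 (3.50 to 3.95), T and NK cell -0.17 (1.36 to 1.56) and neutrophil genes 0.97 (2.09 to 2.25). It was also lower for melanocyte 1.504 (2.96 to 3.21), haematopoietic 1.87 (3.25 to 3.41), inflammatory 1.57 (2.57 to 2.70), osteoblast and matrix 2.22 (3.59 to 3.84), wound 1.99 (2.96 to 3.14) and keratinocyte differentiation genes 6.18 (7.52 to 7.79). Basal keratinocyte genes 9.51 (8.10 to 8.29) and DNA repair genes 4.00 (3.24 to 3.34) were higher, genes above 0 were fewer at 25333 (26388 to 26554) and the TMM factor was lower at 0.907 (1.02 to 1.04). Pecam1 was at 1.64 CPM (62.7 to 66.8), Col1a2 at 35.2 CPM (530 to 692) and Krt14 at 8850 CPM (1990 to 2630).

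The position of skin S-PRT 4 between the untreated mean (0) and the F-PRT mean (1) was 1.05, within the 1.02 to 1.07 of the other S-PRT libraries, which argues against a mislabelled untreated library. Its total of 18.86 megacounts lay within the range of the group and argues against sequencing depth. Of 8 lists of dermal and vascular cell types 6 were lower than in each of the other 11 skin libraries, while adipocyte and TGF-beta response genes were within their range. Less dermis in the sample, a loss of dermal cells in that mouse and a fault of the preparation cannot be told apart, since 1 library shows them. No biological explanation was tested.

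The interferon response list was higher in F-PRT than in S-PRT bone with a median of 0.57 (adjusted p = 1.79e-77, but 0.0525 with an estimated correlation and 0.143 by fry). The list was picked for standing out among 39. Of the 35 splits of the 8 libraries 1 gave it a median as large (highest other 0.423). Likewise 1 of the 35 gave any list a p as small (minus log10 78.3, highest other 50.7). The labelled split thus ranked first with the pick among the lists of this contrast counted. Chance is not excluded, since 1 of 35 is the least this test can give and the same contrast in skin was searched too. A single library and more macrophages and monocytes are argued against as the whole cause, since the lowest median on leaving out each of the 12 libraries was 0.457 and the median was 0.409 with the macrophage list as a covariate (interquartile range 0.255 to 0.617, before it 0.374 to 0.803), with 0 genes in both lists. Skin cells in the bone F-PRT libraries are argued against, since skin RNA made up 0.281% of the difference for the median gene. A response that differs with the beam and a difference in other cell types were not tested and stay open.

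In irradiated skin 12 satellite-like gene models summed to 51.2 CPM against 0.812 CPM untreated (63.1-fold), and Ms4a10 was at 4.89 CPM against 4 counts over the untreated libraries. Bone RNA in the irradiated skin libraries is argued against, since 11 bone-specific genes stood at 0.021 of the level that a bone share of 5.46% would give. Reads shared between near-identical repeat models are argued against, since such reads move between models, while the sum in the lowest irradiated library was 15.4 times that in the highest untreated library. Genomic DNA is argued against for Ms4a10, since 692 olfactory and vomeronasal receptor genes, summing to 41.2 ± 4.87 CPM against 33.9 ± 10.4 CPM (a ratio of 1.21), gained per gene 0.00216 of what Ms4a10 gained. For the models genomic DNA and a change of satellite transcription cannot be told apart, since a receptor baseline this high would hide the small share of DNA that repeats in many copies need, and no biological explanation was tested.

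In skin, 1 of the 35 splits of the samples gave 455 genes for F-PRT against Untreated, with 1 gene as the highest other, so that chance can be excluded at 0.05. For S-PRT against Untreated 2 of the 35 splits gave as many as 827, the other, which exchanges S-PRT 4 and Untreated 1, giving 1297, so that chance could not be excluded and the count points to a structure of the samples. For F-PRT against S-PRT 35 of the 35 gave as many as the real 0, with 0 as the highest other (edgeR; 522 at an unadjusted p under 0.05, 2 with DESeq2, 0 with voom). In bone 1 of the 35 splits gave 6161 and 1 gave 5380, with 185 and 322 as the highest others, and chance can be excluded, while 3 of the 35 gave as many as the 1 gene between the beams, with 29 as the highest other. For the difference between skin and bone 1 of the 26 splits gave 2212 and 1 gave 1961, with 70 and 392 as the highest others, and 26 of the 26 gave 0 between the beams (edgeR, 730 at an unadjusted p under 0.05, 1 with DESeq2). These splits shuffled the treatment labels within each tissue, which removes the effect in both. They do not test equal effects in skin and bone, so no conclusion on a tissue difference is drawn from them.

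For gene lists past the test, 1 of the 35 splits gave the 22 of skin F-PRT against Untreated, with 21 as the highest other. Chance is not excluded, since 1 of 35 is the least this test can give, the margin was 1 list and the other comparisons were searched too. Leaving out each library gave 17 to 23 lists there, and with an estimated correlation 1 list passed. Nor could chance be excluded in the other comparisons. For skin S-PRT 8 of the 35 splits gave as many as 25 (highest other 31). Between the beams in skin 33 gave as many as 18 (highest other 29). The adipocyte list, higher in F-PRT than in S-PRT skin with a median of 0.522, gave a median as large in 3 of the 35 splits (highest other 0.6785), so that chance could not be excluded there. In bone 3 of the 35 gave as many as 29 for F-PRT (highest other 30), 3 as many as 29 for S-PRT (highest other 30) and 26 as many as 15 between the beams (highest other 26).

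The effect differed between skin and bone by an interaction test for 2212 genes after F-PRT and 1961 after S-PRT. After F-PRT the named differences (log2, skin minus bone) were Gria3 4.22, Syne1 2.92, Mpig6b 2.71, Ifnlr1 3.82 and Adpgk 2.71, and after S-PRT Gria3 4.24, Mpig6b 2.99, Syne1 2.69, Ppbp 3.45 and Ifnlr1 3.72.

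Other libraries stood apart from their group in single measures. Skin S-PRT 1 had 22.09 megacounts (18.8 to 19.15) and 565 CPM of Ccng1 (305 to 320). Skin Untreated 1 had 10.5% of rRNA-like counts (1.21 to 1.39), 3.24% of 7SK (6.04 to 6.74), 2.34% of 7SL (4.84 to 5.62) and 280 CPM of Cdkn1a (135 to 149). Skin Untreated 4 had 78.6% protein-coding counts (80.8 to 81.2), skin Untreated 3 a macrophage list mean of 2.44 (3.67 to 3.88) and skin Untreated 2 an erythroid list mean of 2.25 (1.77 to 1.80). Skin F-PRT 4 had hair follicle 2.57 (1.48 to 1.60) and marrow stroma 5.42 (5.32 to 5.33) list means. Bone Untreated 1 had 6.81% mitochondrial counts (2.81 to 3.12) and a marrow stroma mean of 5.46 (5.85 to 5.91). Bone S-PRT 2 had 5.73% mitochondrial counts (4.34 to 4.54) and a T and NK cell mean of 2.50 (3.04 to 3.13), bone S-PRT 1 an oxidative phosphorylation mean of 5.74 (5.41 to 5.47). Bone F-PRT 3 had 6.39% mitochondrial counts (4.1 to 4.4) and a B cell mean of 4.03 (4.34 to 4.40), and bone F-PRT 2 had 2.41% of 7SK (1.9 to 1.95).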

How the results depend on the processing

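The fits without the libraries in doubt, without 7SK, 7SL and rRNA-like models, and with the keratinocyte covariate were chosen after the data were seen; the other alternatives were planned. For named genes the fits that left out each library gave 2880 values, of which 2776 kept direction and side of the threshold, 68 no longer passed and 36 came to pass. For lists that had passed they gave 1656 values, of which 1520 kept both, 126 no longer passed and 10 reversed. RLE scaling kept 240 of 240 gene calls. Except where fewer libraries or another test made the change, the cause was not tested.

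On leaving out each library, the genes changed ranged from 216 to 1477 in skin F-PRT against Untreated, from 452 to 2270 in skin S-PRT against Untreated, and from 0 to 1 in skin and in bone F-PRT against S-PRT. Lists past the test between the beams in bone ranged from 11 to 25. The correlation of the F-PRT and S-PRT effects ranged from 0.694 to 0.819 in skin and from 0.872 to 0.92 in bone.

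With DESeq2 the genes changed were 940 in skin F-PRT, 1487 in skin S-PRT, 2 between the beams in skin, 21 between the beams in bone and 1 in the difference between tissues for F-PRT against S-PRT. With voom they were 2623 in skin F-PRT and 3102 in skin S-PRT. With the 8 compared libraries they were 1215 in skin F-PRT, 305 in skin S-PRT and 0 between the beams in bone. Without a filter 11 passed between the beams in bone, and the correlation was 0.563 in skin and 0.633 in bone; with the stricter filter it was 0.936 in bone. With the controls split it was 0.439 in skin and 0.725 in bone. With the muscle covariate 0 passed between the beams in bone (edgeR), and with the keratinocyte covariate 2660 in bone F-PRT and 0 between the beams.

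Without the libraries in doubt 2704 genes changed in skin F-PRT, 4509 in skin S-PRT and 3655 in the difference between tissues after S-PRT; 8 lists passed between the beams in bone, and the correlation in bone was 0.886. With an estimated correlation the lists that passed were 1 in skin F-PRT, 1 in skin S-PRT, 0 between the beams in skin, 2 in bone F-PRT, 2 in bone S-PRT and 0 between the beams in bone. With fry they were 4 in skin F-PRT, 4 in skin S-PRT, and 0 between the beams in each tissue.

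The labels give no pairing by replicate number, and the values gave no steady sign of one: between skin F-PRT and S-PRT libraries of the same number the correlation was 0.093 to 0.449, with its own number the closest for 3 of 4, and between skin and bone Untreated it was -0.489 to -0.2. The mean correlation of same-numbered libraries between skin F-PRT and S-PRT was 0.243. With the replicate number as a block 299 genes changed in skin F-PRT, 0 between the beams in bone (edgeR), 1236 in the difference between tissues after F-PRT and 1090 after S-PRT. Named genes on the other side of the threshold with the block were Cdkn1a, Sprr2i and Cyc1 in skin F-PRT against Untreated (adjusted p = 0.0541, 0.0544 and 0.0338) and Krt26, Atp5j and Atp5o in skin S-PRT against Untreated (0.0662, 0.0587 and 0.0497). In bone they were Col1a1 in F-PRT against Untreated (0.0644) and Slfn4 between the beams (0.141).

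Some list tests reversed in direction, given here by their medians. With the muscle covariate skeletal muscle was -0.148 in skin S-PRT against Untreated and 0.059 between the beams in skin. In skin S-PRT against Untreated without the libraries in doubt keratinocyte differentiation was 0.14 and dendritic cell 0.06; on leaving out each library they ranged from -0.338 to 0.025 and from -0.664 to -0.126, each highest without S-PRT 4, where the test reversed. Between the beams in skin without the libraries in doubt the medians were senescence -0.062, collagen -0.212, T and NK cell -0.008, dendritic cell -0.132, mast cell -0.377 and nerve -0.066. On leaving out each library they ranged from -0.069 to 0.287 for senescence, -0.212 to 0.331 for collagen, -0.041 to 0.286 for T and NK cell, -0.132 to 0.442 for dendritic cell, -0.378 to 0.449 for mast cell and -0.066 to 0.483 for nerve, each lowest and reversed without S-PRT 4. Skeletal muscle ranged from -3.017 to 0.412 there, reversed without S-PRT 1. Between the beams in bone osteoblast ranged from -0.245 to 0.028, reversed without F-PRT 3, and with the keratinocyte covariate keratinocyte differentiation was -0.073 and erythroid 0.107.

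In the simulated data edgeR recovered 4.48% of genes changed 1.5-fold in skin F-PRT against Untreated and 34.3% in bone, so that depth and spread limit what smaller changes these counts show.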

Other observations

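Rag1, chosen after its values were seen, fell in F-PRT bone from 63.1 to 2.17 CPM. Among satellite-like models Gm10800 (chromosome 2, 98666547 to 98667301) was at 16.7 CPM in irradiated and 0.292 CPM in untreated skin, and at 491 CPM in irradiated and 3080 CPM in untreated bone. The ratio of Gm10800 to Gm10801 was 1.09 in skin and 3.36 in bone. The olfactory receptor gene Olfr1318 was at 2.31 CPM in irradiated and 0.0421 CPM in untreated skin.

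Estimated skin RNA shares of bone libraries are given above. The voom quality weights were lowest in skin S-PRT 4 (0.122) and skin Untreated 1 (0.194).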
